A study of Escherichia coli with 15 samples.

How the data were processed

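The 15 libraries were amplicons of the hok/Sok locus from colony DNA of strain MG1655, in 3 groups of 5 biological replicates, sequenced on a MiSeq in overlapping 2 x 300 nt mode, per the labels' protocols. The submitters' processing notes name cutadapt 1.1, BWA 0.7.17, SAMtools 1.9, R 3.5.3 and DESeq2 1.22.2 without saying what each did. Per the file headers, the deposited counts are the number of sequences with each base at each position of the 486 nt amplicon, per biological replicate, over all sequences of that length. In every library the counts of substituted bases add up to the number of sequences, a mean of 1 substitution per sequence. The data are labelled as single substitutions, and each sequence was taken to carry exactly 1 substitution against the parental sequence of its own library. The deposited comparison tables hold, per the file headers, counts summed over replicates, a signal that is the authors' mean normalized count per group, the authors' log2 fold change with its standard error, and the authors' p-value from a Wald test with its adjusted p-value. These tables were used for the side-by-side values in the closing section only, and the signal columns entered no value. In the mut_HdS against WT_HS table the sign of the test statistic is opposite to that of the fold change at 100% of substitutions, and the fold change, whose direction fits the counts, was used.

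Positions are those of the amplicon. The files also number them on the reference of the plasmid R1 parB region, where the amplicon covers 84 to 569 (amplicon position plus 83), and from the hok transcription start at amplicon position 48. The reading frames were read from the wild-type parental sequence: hok from its ATG to its stop codon (52 residues), and mok as the ATG frame that opens upstream and contains the hok start codon (70 residues). The 5 positions at which the parental sequences differ were left out of all comparisons (36 and 41 in the hok promoter, 183 to 185 in the Sok promoter), which left 481 positions with 3 substitutions each, or 1443. Depth was 113626 to 187640 sequences in WT_HS, 20205 to 96714 in mut_HdS and 62391 to 177626 in mut_dHdS, all positions included. Of the 1443 substitutions, 56 to 541 were not seen in a given mut_HdS library and 16 to 57 in a library of the other groups. The 10 most abundant substitutions took 12.6% to 30.0% of the sequences of a mut_HdS library and 12.7% to 15.7% of the others. PCR sequences without molecular identifiers are not independent molecules, so the binomial intervals given (95%, Wilson) cover counting error only. Replicates of a group differed by more than counting error, with a chi-squared per degree of freedom of 5.76 to 43.9 between libraries of a group. The library is the replicate in every test but those of the closing section that compare substitutions with one another.

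Counts per substitution were fitted in edgeR 4.0.16 (R 4.3.3) with all 15 libraries and 3 groups, TMM library factors, its default filter on low counts by group (1096 substitutions kept), robust dispersions and the quasi-likelihood F test. P-values were adjusted over the substitutions tested (Benjamini-Hochberg), and an adjusted p under 0.05 is a call. The standard error printed with a log2 fold change is the size of the change divided by the square root of F. TMM factors were 0.413 to 1.05 in mut_HdS and 1.04 to 1.43 in the other groups. For each class the share of sequences per library was compared by an exact two-sided permutation test of the difference in means (252 assignments, smallest p 0.00794), adjusted over the 18 classes of a comparison. Lists were tested as sets with camera (limma 3.58.1) on voom values, with the preset correlation 0.01 and with an estimated one, adjusted over the lists. Shares printed per substitution are means and SD over 5 libraries of the percent of sequences at the compared positions.

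The tests, lists, naming rule and alternatives were fixed before the data were examined, except where a test or name is said to have been chosen later. The lists were hok start codon, the 20 nt before it, hok nonsense, hok missense in residues 5 to 25 and of these the changes to aspartate, glutamate, lysine, arginine or proline, hok missense outside residues 5 to 25, missense at cysteine codons, hok synonymous, hok stop codon loss, mok start codon, mok nonsense, missense and synonymous outside hok, upstream of the mok start codon, after the hok stop codon, the bases that differ between the parents with 10 nt on each side, transitions and transversions. Named for mut_HdS against mut_dHdS were the 10 highest and 10 lowest calls whose libraries did not overlap, every tested hok start codon and nonsense substitution, and the 5 largest called hok synonymous and Shine-Dalgarno window changes. Only 4 lower calls and 2 hok synonymous calls met the rule. For the other comparisons the 5 highest and 5 lowest were named, of which WT_HS against mut_dHdS had 1 and 1. Substitutions outside this rule are said to have been named after their values were seen.

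Alternatives changed 1 choice at a time: RLE factors, library totals, DESeq2 1.42.0, limma-voom with group weights, no count filter, at least 50 counts in 5 libraries, the 10 libraries of the comparison only, replicate number as a block, an added 2-fold threshold, and each library left out in turn. Class shares were repeated without the 10 most abundant substitutions of each library, over distinct substitutions with at least 10 counts, within replicate numbers and with each library left out. Thinning every library to 19693 sequences at the compared positions was added after the data were seen. Once group means were removed, the mean correlation across substitutions was 0.0205 between mut_HdS and mut_dHdS libraries of the same replicate number and -0.00492 between those of different numbers. It was 0.0264 and -0.00662 for WT_HS with mut_dHdS, and -0.00600 and 0.00204 for WT_HS with mut_HdS. Same-number libraries were not called more alike (exact one-sided permutation p = 0.2, 0.15 and 0.725, a test chosen after the data were seen), and no block entered the tests reported. The fit was tested on simulated counts, drawn from the means of the WT_HS and mut_dHdS libraries and the depths and spread of every library's own group with 200 substitutions changed in mut_HdS. In mut_HdS against mut_dHdS, with 1106 tested, edgeR recovered 2 of 50 raised 2-fold, 31 of 52 raised 4-fold and 51 of 51 raised 16-fold, and 9 of its 117 calls (7.69%) were unchanged substitutions. DESeq2 gave 15 unchanged of 131 calls and limma-voom 14 of 116. In mut_HdS against WT_HS, 8 of 120 edgeR calls were unchanged, and with no change simulated between WT_HS and mut_dHdS edgeR, DESeq2 and limma-voom called 0 and had no change to recover. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 did the remaining computation.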

Results

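The hok/Sok locus of plasmid R1 encodes Hok, a small membrane-acting toxin, and Sok, an antisense RNA that blocks translation of the hok mRNA. An overlapping leader frame, mok, must be translated for hok to be translated. Mutagenised PCR libraries of the locus had been transformed into Escherichia coli MG1655, between galM and gpmA, and the locus was sequenced from colony DNA as an amplicon of 486 nt. There were 3 libraries with 5 biological replicates each: the wild-type locus (WT_HS), the locus with a mutated Sok promoter (mut_HdS), and the locus with mutated hok and Sok promoters (mut_dHdS). Each counted sequence was taken to carry exactly 1 substitution against the parental sequence of its own library. The replicates held 113626 to 187640 such sequences in WT_HS, 20205 to 96714 in mut_HdS and 62391 to 177626 in mut_dHdS. The 5 positions at which the parents differ were set aside, which left 481 positions and 1443 possible substitutions, of which 1096 had enough counts to be tested. A substitution is written as the reference base, its position in the amplicon and the new base. Position 48 is the first base of the hok mRNA, the mok frame covers positions 163 to 375, and the hok frame covers positions 221 to 379. A protein change follows in parentheses where it helps.

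The comparison of mut_HdS with mut_dHdS asks which single-base changes became more frequent among colonies when Sok was not made from its promoter but the hok promoter was intact. Against mut_dHdS, 130 substitutions at 97 positions rose in mut_HdS and 7 fell. Those that rose had log2 fold changes of 1.13 to 6.06 with a median of 4.10. The substitutions called higher in this comparison made up 56.2% ± 20.2 (SD, n = 5) of all sequences in mut_HdS, 8.08% ± 0.294 in mut_dHdS and 8.88% ± 0.738 in WT_HS, although the mut_HdS and mut_dHdS values are not independent of the calls. The mut_HdS libraries stood apart from one another, at 63.3% (95% Wilson interval 62.9 to 63.8), 42.3% (41.95 to 42.58), 28.2% (27.9 to 28.5), 73.6% (73.2 to 74.0) and 73.6% (73.0 to 74.3) in replicates 1 to 5. Their hok synonymous shares were 3.18% (3.02 to 3.36), 5.67% (5.53 to 5.82), 7.64% (7.47 to 7.82), 2.62% (2.48 to 2.77) and 3.02% (2.79 to 3.26) in the same order. Among substitutions whose 5 mut_HdS libraries all lay above the 5 mut_dHdS libraries, A224G (K2E in Hok) rose most, from 0.0754% ± 0.0292 of sequences to 1.63% ± 0.814 (n = 5 each). Its log2 fold change, fitted with composition (TMM) factors, was 5.87 ± 0.75 (SE, edgeR adjusted p = 8.95e-05). G393T, which lies after the hok stop codon, rose by 5.70 ± 0.80 (adjusted p = 0.000139) and A153G, upstream of mok, by 5.31 ± 0.91 (adjusted p = 0.000557). The test was edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, in which 228 substitutions had an unadjusted p under 0.05. Of the 137 calls, 85 had fully separated libraries, and 8.58% of all tested substitutions were separated where chance gives 0.794%. The calls are relative to a median log2 fold change of -0.16 over all tested substitutions. With library totals in place of composition factors this median was -1.07, and 103 substitutions were then called higher and 299 lower. Counts of higher and lower calls by list below are with composition factors unless stated, and the balance over the whole comparison depends on that choice. Shares printed with a log2 fold change are without these factors. In comparisons of mut_HdS, the printed log2 fold change lies above that of the shares.

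**Figure D1:**
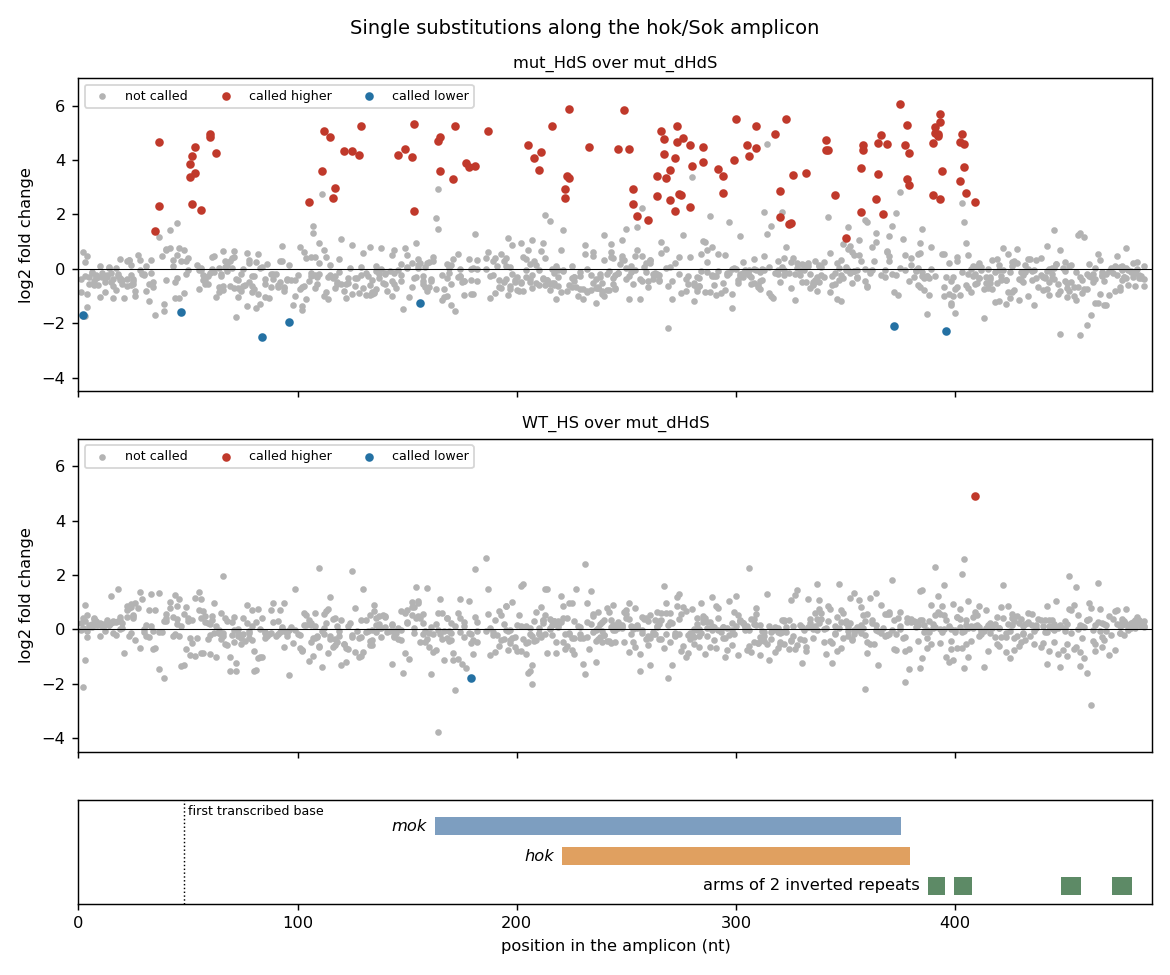
Log2 fold change of each tested substitution (points) against its position in the amplicon (nt), for mut_HdS over mut_dHdS (top) and WT_HS over mut_dHdS (middle), with the reading frames and inverted repeat arms to scale (bottom). The 130 higher and 7 lower calls of the top panel stand against 1 higher and 1 lower call in the middle panel.

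Substitutions that truncate Hok rose together. Of 22 tested hok nonsense substitutions, 15 rose and 7 were not called, with 20 higher when adjusted over the list alone, and their median log2 fold change was 3.39. G249A (W10*) rose by 5.85 ± 0.83 (adjusted p = 0.000139), G341T (E41*) by 4.73 ± 0.70 (adjusted p = 0.000186), C233T (R5*) by 4.48 ± 0.67 (adjusted p = 0.000191) and C299T (R27*) by 4.00 ± 0.61 (adjusted p = 0.000212). Called stops reached to the end of the protein, where C364G (Y48*) rose by 2.55 ± 0.62 (adjusted p = 0.00854) and G365T (E49*) by 3.49 ± 0.97 (adjusted p = 0.0214). The uncalled stops included T292G (Y24*) at -0.09 ± 0.30 and G250A (W10*) at 1.47 ± 0.49 (adjusted p = 0.0629), and G250A already held 0.709% of mut_dHdS sequences. As a class, hok nonsense made up 5.23% ± 1.60 of sequences in mut_HdS and 2.05% ± 0.361 in mut_dHdS (n = 5, exact two-sided permutation p = 0.00794, the smallest that 5 against 5 libraries can give, adjusted p = 0.011). The shift of the list against the other substitutions held with an estimated correlation (camera adjusted p = 0.0354). Leaving out 1 library gave 11 to 18 nonsense calls. T292A (Y24*) had a log2 fold change of 1.00 (adjusted p = 0.348) without replicate 4 of mut_HdS, and T268A, C325A, G332T and G365T each lost the call without at least 1 library, with adjusted p of up to 0.272, 0.098, 0.0549 and 0.128. C364G kept its call with any 1 library left out but lost it with library totals (adjusted p = 0.056), as did T268A and C325A (0.0648 and 0.298). With the replicate block G365T lost its call (adjusted p = 0.0557), as did T268A, T292A, C325A and G332T.

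The start and stop codons of hok differed from base to base. At the start codon, T222C rose by 2.93 ± 0.53 (adjusted p = 0.00078), G223T by 3.42 ± 0.78 (adjusted p = 0.00527) and T222A by 2.59 ± 0.73 (adjusted p = 0.0225). Of these, G223T also stops mok (E21*), T222A changes a mok residue (H20Q) and T222C leaves the mok protein unchanged (H20H). The other 4 start codon substitutions tested were not called: A221G at 1.43 ± 0.67, A221T at -0.05 ± 0.74, A221C at -0.07 ± 0.40 and G223A at -0.81 ± 0.53. The start codon counts were the same adjusted over the list alone, its share of sequences was not called (0.599% in mut_HdS and 0.428% in mut_dHdS, exact permutation p = 0.0714), and T222A lost its call without any 1 of 6 libraries (replicates 3 and 5 of mut_HdS and 1, 2, 4 and 5 of mut_dHdS), with adjusted p of up to 0.0954. Of 7 substitutions that remove the hok stop codon, 5 rose, also when adjusted over the list alone. They were A378G at 5.30 ± 0.71, T377C at 4.54 ± 0.68, G379C at 4.25 ± 1.20, A378T at 3.30 ± 0.89 and G379T at 3.09 ± 0.70. Stop codon loss went from 0.384% ± 0.0536 of sequences in mut_dHdS to 2.06% ± 0.748 in mut_HdS (n = 5, exact permutation adjusted p = 0.011), and its camera call held with an estimated correlation (adjusted p = 0.0354). Without replicate 4 of mut_dHdS the number of stop codon loss calls was 3. It was also 3 with limma-voom, with the libraries of the comparison only and with the replicate block. With at least 50 counts in 5 libraries, and when thinned, it was 2. All stop codon substitutions but A378G were named after their values were seen.

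Synonymous changes in hok gave few calls. Of 94 tested, 2 rose, and neither passed when adjusted over the list alone. They were A367G (E49E) at 2.00 ± 0.47 (adjusted p = 0.00709) and A274T (T18T) at 2.74 ± 0.86 (adjusted p = 0.046), and both change an amino acid of mok (I69V and T38S). A274T lost its call without any 1 of 9 libraries: replicates 4 and 5 of WT_HS, 4 and 5 of mut_HdS and each replicate of mut_dHdS, with adjusted p of up to 0.41. The hok synonymous share of sequences went from 9.19% ± 0.306 in mut_dHdS to 4.43% ± 2.16 in mut_HdS (n = 5, exact permutation adjusted p = 0.011). Shares of a library add up to 100%, so a lower share of a class here and below does not separate a fall of its members from a rise of others. With library totals alone, 27 synonymous substitutions were called lower and those 2 higher calls were lost. That scaling called 299 of all 1096 tested substitutions lower, so these lower calls are not particular to synonymous changes.

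Shares were also taken over distinct substitutions with at least 10 sequences in a library in place of sequences. Counted so, the shares of hok nonsense and of hydrophobic segment changes to aspartate, glutamate, lysine, arginine or proline were still called higher in mut_HdS than in mut_dHdS. Those of stop codon loss, the whole segment, cysteine changes, hok synonymous, mok start codon, mok nonsense, missense and synonymous changes, the region after the hok stop codon and transitions were not called. The other 2 of the 4 shares that passed, where 14 of 18 had, were hok missense outside the segment, 4.47 points higher in mut_HdS, and the region upstream of mok, with a difference of -6.09 points. The cutoff of 10 sequences depends on depth: 227 to 951 substitutions reached it in a mut_HdS library and 921 to 1164 in a mut_dHdS library. Unequal depth can therefore move these shares, and its part was not separated.

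**Figure D2:**
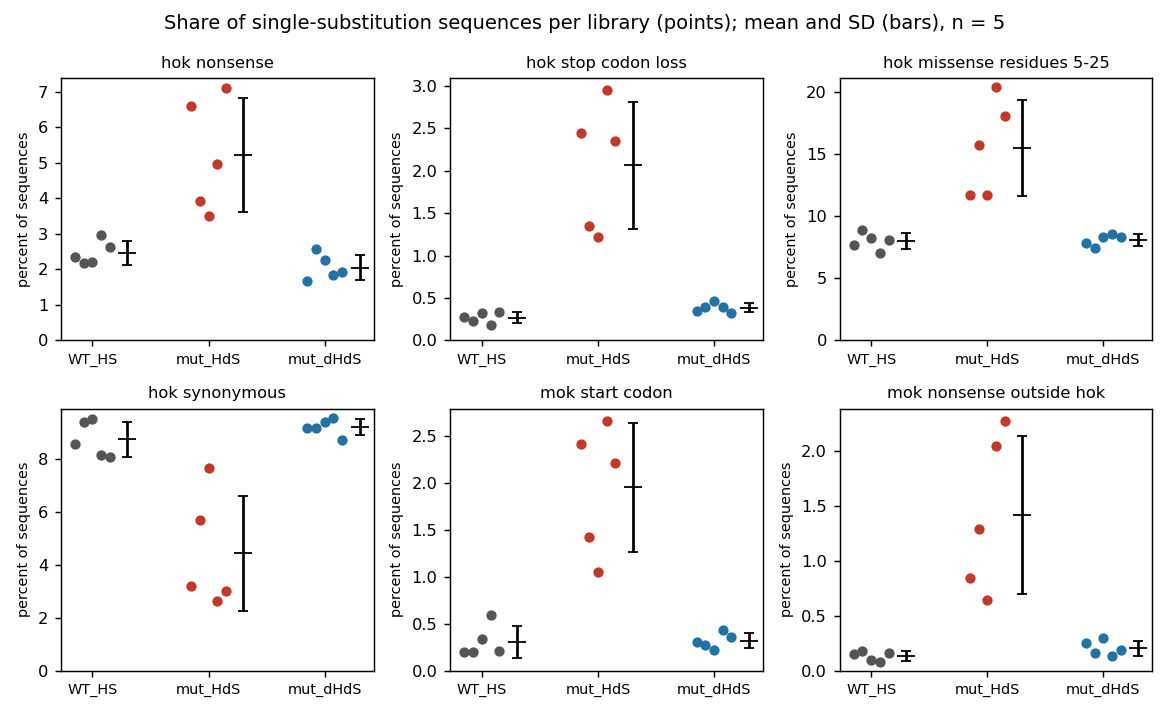
Percent of single-substitution sequences in 6 classes of hok and mok substitutions, per library (points), with mean and SD (bars, n = 5) for WT_HS, mut_HdS and mut_dHdS. Nonsense rose to 5.23% and stop codon loss to 2.06% in mut_HdS, while synonymous sequences made up 4.43% against 9.19% in mut_dHdS.

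Missense substitutions rose at part of the Hok residues. In the hydrophobic segment, residues 5 to 25, 24 of 106 tested missense substitutions rose, with 26 higher and 1 lower when adjusted over the list alone, and the 24 calls lay at 12 of its 21 residues. T18 had 4 called changes, with C273T (T18I) at 5.27 ± 0.77 (adjusted p = 0.000186), and C16 had 3. Substitutions of the segment to aspartate, glutamate, lysine, arginine or proline rose at 9 of 24 tested, or 10 higher and 1 lower adjusted over the list alone, and their share went from 2.59% ± 0.0625 to 7.84% ± 3.13 (n = 5, exact permutation adjusted p = 0.011). Their camera call held with an estimated correlation (adjusted p = 0.0354), while that of the whole segment had an adjusted p = 0.0954 with an estimated correlation. The segment's share went from 8.08% ± 0.456 to 15.5% ± 3.86 (n = 5, exact permutation adjusted p = 0.011). At hok cysteine codons 5 of 18 substitutions rose, also when adjusted over the list alone. They were T266C (C16R) at 5.05 ± 0.66, G267T (C16F) at 4.76 ± 0.99, T251C (C11R) at 4.42 ± 0.65, G267A (C16Y) at 4.21 ± 0.59 and T253G (C11W) at 2.39 ± 0.57, named after their values were seen. All lie in the segment, and at C31, outside it, 0 of 6 tested changes rose (highest log2 fold change 0.49). The cysteine share went from 1.75% ± 0.289 to 5.46% ± 2.21 (n = 5, exact permutation adjusted p = 0.011), but its camera adjusted p was 0.0574, and without the 10 most abundant substitutions of each library its share was no longer called.

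Outside the segment, 22 of 140 hok missense substitutions rose and 1 fell, with the same counts adjusted over the list alone, and the 22 lay at 14 of 30 residues tested. T323C (Y35H) rose by 5.49 ± 0.64 (adjusted p = 8.95e-05), G300T (R27L) by 5.51 ± 1.29 (adjusted p = 0.00663) and T309C (L30P) by 5.27 ± 0.74 (adjusted p = 0.000139), from 0.131% ± 0.0602 of sequences to 1.92% ± 1.17. G372A (G51D) fell by 2.08 ± 0.57 (adjusted p = 0.0193), a call that was lost without replicate 3 of mut_HdS (adjusted p = 0.0515). The list shifted upward with an estimated correlation (camera adjusted p = 0.0354) but not with the preset one (adjusted p = 0.0636). Its share of sequences was 21.8% ± 2.71 in mut_HdS and 25.2% ± 0.961 in mut_dHdS (n = 5, exact permutation adjusted p = 0.0306). That difference was lost without any 1 of the mut_dHdS replicates, and it turned to 4.26 points higher in mut_HdS without the 10 most abundant substitutions of each library (exact permutation adjusted p = 0.0143).

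Substitutions that stop mok before the hok frame rose as well. Of 5 tested mok nonsense substitutions outside hok, 4 rose, also when adjusted over the list alone: C205T (Q15*) at 4.55 ± 0.55, G211T (E17*) at 4.31 ± 0.86, G208T (G16*) at 4.08 ± 0.81 and C178T (Q6*) at 3.76 ± 0.65. Their share went from 0.204% ± 0.0665 to 1.42% ± 0.720 (n = 5, exact permutation adjusted p = 0.011), and the camera call was lost with an estimated correlation (adjusted p = 0.112). At the mok start codon 3 of 7 rose, with 5 higher when adjusted over the list alone: G165A at 4.83 ± 0.79, T164C at 4.70 ± 0.73 and G165T at 3.59 ± 0.77. Its share went from 0.318% ± 0.0812 to 1.95% ± 0.686 (n = 5, exact permutation adjusted p = 0.011), with a camera call that held with an estimated correlation (adjusted p = 0.0354). Of 83 mok missense substitutions outside hok, 4 rose, or 3 adjusted over the list alone: C172A (P4T) at 5.26 ± 0.68, C187T (L9F) at 5.08 ± 0.75, G181A (D7N) at 3.79 ± 0.72 and T171A (S3R) at 3.30 ± 0.95. The mok missense share went from 8.79% ± 0.821 to 4.19% ± 1.53 (n = 5, exact permutation adjusted p = 0.011). Of 32 mok synonymous substitutions 3 rose, also when adjusted over the list alone: A216G (E18E) at 5.25 ± 0.69, T177C (H5H) at 3.87 ± 0.51 and A210G (G16G) at 3.65 ± 0.64. Their share went from 2.61% ± 0.289 to 5.04% ± 1.86 (n = 5, exact permutation adjusted p = 0.011), a call lost without any 1 of replicates 2, 3 and 5 of mut_dHdS, and a difference that turned to -0.284 points without the 10 most abundant substitutions (exact permutation adjusted p = 0.295). Other than C172A and the Shine-Dalgarno window substitutions, the mok changes were named after their values were seen.

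In the 20 nt before the hok start codon, which hold the Shine-Dalgarno sequence, 5 of 51 substitutions rose, also when adjusted over the list alone. They were A216G, from 0.207% ± 0.0819 of sequences to 2.87% ± 2.13, and C205T, G211T, G208T and A210G, with the changes given above. Of these, 3 also stop mok and 2 leave the mok protein unchanged. The window's share of sequences was not called (7.27% ± 1.26 in mut_HdS and 7.01% ± 1.07 in mut_dHdS, n = 5, exact permutation p = 0.706), nor was its camera shift (adjusted p = 0.903). Without the 10 most abundant substitutions of each library the difference in share turned to -1.78 points, which was called (exact permutation adjusted p = 0.0143).

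Calls outside both reading frames lay in short stretches. Upstream of the mok start codon 28 of 344 substitutions rose and 5 fell, or 27 and 5 adjusted over the list alone. A stretch at positions 51 to 63, near the start of the mRNA, held 10 higher calls among 27 tested, with log2 fold changes of 2.16 to 4.95. Positions 105 to 129 held 10 among 56 tested (2.47 to 5.26), positions 146 to 153 held 5 among 18 tested (2.13 to 5.31) and positions 35 to 37, upstream of the mRNA start, held 3 among 5 tested (1.40 to 4.65). The substitutions that fell upstream were G84T at -2.50 ± 0.63, G96T at -1.96 ± 0.54, A2T at -1.69 ± 0.45, C47T at -1.58 ± 0.37 and C156T at -1.24 ± 0.38. G96T and A2T lost the call without replicate 3 of mut_HdS (adjusted p = 0.0512 and 0.0989). Around the bases that distinguish the parental promoters, 9 of 90 substitutions rose and 1, C47T, fell, with the same counts adjusted over the list alone. Neither share of sequences was called: 5.51% ± 0.418 against 5.85% ± 0.500 around the promoter bases (n = 5, exact permutation p = 0.357), and 22.8% ± 1.18 against 21.9% ± 0.907 upstream of mok (n = 5, exact permutation p = 0.206), which turned to a called difference of -3.41 points (adjusted p = 0.0476) without the 10 most abundant substitutions of each library. The stretches, and G84T and C156T, were singled out after their values were seen.

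After the hok stop codon 17 of 248 substitutions rose and 1, G396T, fell by 2.30 ± 0.58, with the same counts adjusted over the list alone. Of the 17, 16 lay in the arms of an inverted repeat, positions 388 to 395 (AGGCGGGC) and 400 to 407 (GCCCGCCT), where 41 were tested. The other was T409A at 2.47 ± 0.64. G396T was named after its value was seen. The 9 tested substitutions of the loop between the arms and the 40 in the arms of a second inverted repeat, positions 449 to 457 and 472 to 480, gave no higher call with edgeR, where the whole comparison had 228 unadjusted p under 0.05, 181 calls with DESeq2 and 115 with limma-voom. The share of sequences after the stop codon went from 20.8% ± 0.869 to 15.0% ± 2.61 (n = 5, exact permutation adjusted p = 0.011). Camera gave no shift for the list (adjusted p = 0.0761), nor for the upstream list (0.0771), the promoter bases (0.978), hok start codon (0.121), hok synonymous (0.118) or mok missense and synonymous changes (0.189 and 0.725). Transitions made up 65.5% ± 6.12 of sequences in mut_HdS and 50.8% ± 3.75 in mut_dHdS (n = 5, exact permutation adjusted p = 0.011), with 59 of 481 transitions and 71 of 615 transversions called higher, also when adjusted over each list alone. The difference in transitions was no longer called without the 10 most abundant substitutions of each library. The counts of the 2 lists depend on the count filter: with at least 50 counts in 5 libraries 32 of 91 higher calls were transversions, and when thinned 32 of 92.

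**Figure D3:**
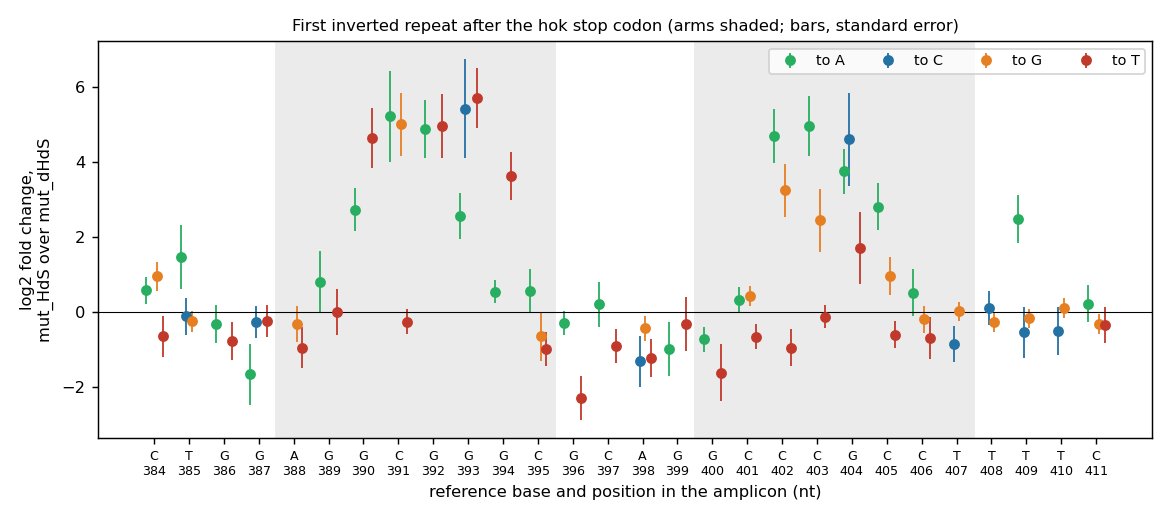
Log2 fold change of mut_HdS over mut_dHdS (points, with SE) at each position of the first inverted repeat after the hok stop codon, by new base, with the arms shaded. Of the higher calls shown, 16 lie inside the arms and T409A lies outside them, and the changes from C to T in the arms lie at or below -0.13.

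The comparison of mut_HdS with WT_HS asks what the loss of the Sok promoter alone changed. Against WT_HS, 129 substitutions rose in mut_HdS and 13 fell, with a median log2 fold change of 3.89 among those that rose. G393T after the hok stop codon rose by 6.21 ± 0.82 (adjusted p = 9.36e-05), C205T (mok Q15*) by 6.15 ± 0.60 (adjusted p = 1.79e-05), T318C (I33T) by 5.79 ± 0.67 (adjusted p = 3.58e-05), T323C (Y35H) by 5.60 ± 0.64 (adjusted p = 3.58e-05) and T266C (C16R) by 5.41 ± 0.68 (adjusted p = 8.44e-05). T266C went from 0.131% ± 0.0545 of WT_HS sequences to 2.34% ± 1.46 in mut_HdS (n = 5 each). Among those that fell were G26A at -1.78 ± 0.49 (adjusted p = 0.0197), A2T at -1.73 ± 0.45 (0.0132), T15A at -1.71 ± 0.40 (0.00612), C156T at -1.66 ± 0.38 (0.00537) and G170C (mok S3T) at -1.54 ± 0.43 (0.0399). A2T lost its call without replicate 3 of mut_HdS (adjusted p = 0.0704), and G170C without replicates 2, 4 or 5 of WT_HS or 1, 2, 3 or 5 of mut_HdS (adjusted p of up to 0.104).

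By group, 13 of 22 hok nonsense substitutions rose against WT_HS, or 15 adjusted over the list alone, as did 5 of 7 that remove the hok stop codon, 4 of 7 at the mok start codon, 4 of 5 mok nonsense, 24 of 106 missense substitutions of the hydrophobic segment and 5 of 18 at cysteines. Adjusted over the list alone the segment had 25 and the other 4 groups the same counts. Outside the segment 23 of 140 missense substitutions rose and 1 fell, and of 94 hok synonymous substitutions 3 rose and 1 fell, or 1 and 1 adjusted over the list alone. Upstream of mok 26 of 344 rose and 7 fell (24 and 7 over the list alone), and after the hok stop codon 16 of 248 rose and 2 fell (15 and 2 over the list alone). The share of hok nonsense went from 2.47% ± 0.333 in WT_HS to 5.23% ± 1.60 in mut_HdS, and that of mok nonsense from 0.132% ± 0.0420 to 1.42% ± 0.720 (n = 5, exact permutation adjusted p = 0.011 for both). The hok synonymous share went from 8.73% ± 0.675 to 4.43% ± 2.16 (n = 5, exact permutation adjusted p = 0.011). Of 18 class shares 15 passed adjustment. Camera called 8 lists, of which stop codon loss alone held with an estimated correlation (adjusted p = 0.0304). In 77 of the 142 calls the libraries were separated, where chance gives 0.794% of all tested and 10.6% were observed. The median log2 fold change over all tested substitutions was -0.17, and with library totals it was -0.96, with 106 higher and 257 lower calls. DESeq2 called 146 higher and 79 lower.

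The substitutions that rose in the 2 comparisons overlapped: 117 rose in both, of 130 and 129, where independent draws from 1096 would share 15.3. Both comparisons use the same mut_HdS libraries. With those libraries split between the comparisons, 2 for one and 3 for the other, the median over 10 splits was 89.5 shared, against 11.9 for independent draws. This split was chosen after the data were seen. T409A was called in opposite directions, 2.47 against mut_dHdS (adjusted p = 0.0134) and -2.43 against WT_HS (adjusted p = 0.00948).

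The comparison of WT_HS with mut_dHdS asks whether an intact locus, with its antitoxin, differed from one with neither promoter. Here 1 substitution rose in WT_HS and 1 fell among 1096. T409A, after the hok stop codon, made up 0.174% ± 0.129 of WT_HS sequences and 0.00649% ± 0.000952 of mut_dHdS sequences (n = 5 each), a log2 fold change of 4.91 ± 0.66 (adjusted p = 0.00147). A179G (mok Q6R) made up 0.0462% ± 0.00768 and 0.175% ± 0.0644 (n = 5 each), a log2 fold change of -1.79 ± 0.32 (adjusted p = 0.0198). Hok nonsense, start codon, stop codon loss, missense and synonymous substitutions and mok start codon, nonsense and synonymous substitutions gave no call with edgeR, where 110 of all tested substitutions had an unadjusted p under 0.05. DESeq2 called 14 higher and 13 lower and limma-voom 4 and 6 over the whole comparison. Adjusted over the list alone, mok missense had 3 lower, mok nonsense 2 lower, mok synonymous 1 higher and 1 lower, the promoter bases 1 higher and 3 lower, the Shine-Dalgarno window 2 lower, the region after the hok stop codon 2 higher and 1 lower, and hok synonymous 1 higher. The edgeR calls had separated libraries, as did 3.19% of the tested substitutions, where chance gives 0.794%. Hok nonsense made up 2.47% ± 0.333 in WT_HS and 2.05% ± 0.361 in mut_dHdS (n = 5, exact permutation p = 0.0952, adjusted p = 0.343), and no class share passed adjustment. Substitutions of the hydrophobic segment to aspartate, glutamate, lysine, arginine or proline came nearest, at 2.30% ± 0.123 against 2.59% ± 0.0625 (exact permutation p = 0.00794, adjusted p = 0.143). Camera's calls for transitions and transversions (adjusted p = 0.0261) were lost with an estimated correlation (adjusted p = 0.546). A179G lost its call without replicates 1, 2 or 3 of WT_HS or 1 or 3 of mut_dHdS (adjusted p of up to 0.0783), and leaving out any 1 of the 15 libraries gave 1 to 7 calls.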

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

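The test at the promoter positions was chosen only after the result was seen. The hok promoter positions 36 and 41, at which WT_HS and mut_HdS have the same parental base, were outside the comparisons because mut_dHdS differs there. In mut_HdS, T41C made up 1.19% ± 0.530 of all sequences (SD, n = 5) against 0.0729% ± 0.0315 in WT_HS, a ratio of 16.4. T36C made up 0.415% ± 0.218 against 0.0862% ± 0.0266, T36A 0.166% ± 0.0513 against 0.0512% ± 0.0144, and T41A 0.0549% ± 0.0204 against 0.0180% ± 0.00161. Each of these 4 was higher in 5 of 5 mut_HdS libraries than in any WT_HS library (exact two-sided permutation p = 0.00794, the smallest possible, adjusted p = 0.0119 over 6 substitutions). T36G (p = 0.341) and T41G (p = 0.881) did not differ by the same exact permutation test. T36A and T41A give the parental base of mut_dHdS, while T36C and T41C give the base of no parent. In mut_dHdS the reverse changes, A36T and A41T, made up 0.731% and 0.620%. Over the 5 positions at which the parents differ, changes to another parent's base made up 0.0180% (T41A in WT_HS) to 3.56% (G185C in WT_HS). Carry-over between libraries was not tested, nor was any other technical or biological explanation for these positions.

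A single library stood far from the other 4 of its group in 21 of 237 groups of 5 tested (8.86%). The cutoff gives about 1 in 20 by chance for normal values, which these percents were not shown to be. Of the 21, 20 were among the 57 named substitutions, many of them chosen by their change, so no excess over chance can be read from the count. Intervals are 95% Wilson intervals of the percent of sequences. In WT_HS, the mok synonymous class was high in replicate 4 at 3.31% (3.21 to 3.42, others at most 2.48%). Single WT_HS substitutions were high in replicate 1 for G341T at 0.0560% (0.0448 to 0.0700) and A274T at 0.115% (0.0984 to 0.134), and in replicate 2 for T268A at 0.0770% (0.0633 to 0.0938) and C364G at 0.0973% (0.0817 to 0.116). Replicate 4 was high for A153G at 0.706% (0.658 to 0.758), A221T at 0.123% (0.104 to 0.146) and C306A at 0.323% (0.291 to 0.359). Replicate 5 was high for G300T at 0.240% (0.216 to 0.267), C313A at 0.0824% (0.0687 to 0.0988) and G314T at 0.269% (0.243 to 0.298). In mut_HdS, replicate 1 was high for A221G at 0.526% (0.461 to 0.599), A302T at 1.28% (1.18 to 1.39) and G314T at 1.14% (1.05 to 1.25). There, replicate 3 was high for C325G at 0.0590% (0.0450 to 0.0774), replicate 4 for T292A at 0.134% (0.105 to 0.171) and replicate 5 for A367G at 0.213% (0.158 to 0.288). In mut_dHdS, replicate 3 was high for C47T at 0.320% (0.290 to 0.353), A326T at 0.0697% (0.0564 to 0.0862), G365T at 0.145% (0.125 to 0.168) and C205T at 0.166% (0.145 to 0.191). No explanation was tested for these single-library values.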

How the results depend on the processing

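Thinning to equal depth was chosen only after the data were seen. The cause of each shift below was not tested unless stated. Of the results for named substitutions, 1374 kept their direction and their side of the threshold over all alternatives, 77 lost a call, 21 gained one and none of those run changed direction. Of those for class shares, 608 were kept, 78 lost a call, 6 gained one and 10 changed direction. The count of calls for mut_HdS against mut_dHdS, 137, was 402 with library totals, where the median over all substitutions is -1.07, and otherwise 94 (thinned, with 516 substitutions tested) to 181 (DESeq2), with 123 to 143 when a library was left out. For mut_HdS against WT_HS, 142 became 363 with library totals and 225 with DESeq2, and otherwise stayed at 104 (thinned, or at least 50 counts) to 156 (no filter), with 126 to 155 when a library was left out. For WT_HS against mut_dHdS, 2 became 1 with library totals and with the replicate block, 4 with at least 50 counts, 6 with the libraries of the comparison only, 10 with limma-voom and 27 with DESeq2, and 1 to 7 when a library was left out.

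Class shares past adjustment went from 14 to 4 against mut_dHdS and from 15 to 8 against WT_HS when distinct substitutions with at least 10 counts were taken. Within replicate numbers both went to 0, since the smallest exact permutation p is then 0.0625. Without the 10 most abundant substitutions of each library, 3 shares passed for WT_HS against mut_dHdS, where 0 had. Camera calls with an estimated correlation went from 8 to 1 for mut_HdS against WT_HS and from 2 to 0 for WT_HS against mut_dHdS. Differences that changed direction, mut_HdS minus mut_dHdS in points, were -1.78 for the Shine-Dalgarno window, 4.26 for hok missense outside the segment, -0.284 for mok synonymous and -3.41 upstream of mok without the 10 most abundant substitutions. With distinct substitutions they were 4.47 for hok missense outside the segment and -6.09 upstream. Against WT_HS they were 3.21 for hok missense outside the segment and -0.229 for mok synonymous without the most abundant, and 4.55 and -5.73 for hok missense outside the segment and upstream with distinct substitutions. All of these but the 2 for mok synonymous passed adjustment. Depth limits what can be tested, 516 substitutions when thinned in place of 1096. In simulated counts for mut_HdS against mut_dHdS, with the depth and the spread of each group together, 4% of 2-fold and 59.6% of 4-fold increases were recovered, and the 2 limits were not separated.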

Other observations

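The tests of the uncalled stops, of the PCR pools, of scaling, of errors at inverted repeats, of the C-to-T background and of base pairing at the same position, and the place of A388G among the pair-keeping substitutions, were chosen only after the result was seen. Along Hok, the residue with most called missense changes outside the hydrophobic segment was 46, a methionine, where 4 of 7 tested changes rose in mut_HdS against mut_dHdS, with log2 fold changes of up to 4.55. Residue 49, a glutamate, had 2 of 3, and residues 35 and 41 had 2 of 4 each. These residues were named after their values were seen. In the tables the authors deposited, adjusted p-values at or below 0.05 number 166 for mut_HdS against mut_dHdS (149 higher, 17 lower), 194 for mut_HdS against WT_HS (148 and 46) and 26 for WT_HS against mut_dHdS (10 and 16). Of the calls made here, 135 of 137, 140 of 142 and 2 of 2 were among them with the same direction, on the same libraries.

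Of 22 tested hok nonsense substitutions, 7 were not called higher in mut_HdS. Their number depends on the threshold: adjusted over the list alone, 20 of the 22 were higher. In the authors' deposited table G314T and C313A pass as well (Wald test adjusted p = 0.00152 and 0.0211). G250A, C364A, T292G and C325G do not pass there, and A302T has no p-value. Against truncated proteins of different activity as the whole cause, the called and the uncalled substitution of the same codon differed by over 2 standard errors at 3 of 4 such codons, as for G249A and G250A, both W10*, by 4.38 ± 0.96. The argument rests mainly on W10. It takes both substitutions of a codon to give the same protein. They make different stop codons, and their products were not measured. At Y24 the called T292A fell to 1.00 without replicate 4 of mut_HdS. At Y35 the difference was 2.17 standard errors, and the called C325A lost its call without any 1 of 7 libraries. Against too few counts for the set, the uncalled stops had a median of 511 counts in WT_HS and the called ones 189 (permutation p = 0.0348). WT_HS is on neither side of this comparison, but its libraries entered the same fit, with its count filter and estimate of spread. Single stops such as G314T, at 4.57 ± 1.47, stay open. Miscalled bases present in every library could dilute a change, and the rank correlation across the 22 substitutions between the log2 fold change and the share in WT_HS was -0.23 (permutation p = 0.302), which leaves this open. A difference in activity between codons, and effects of the mok changes that come with each stop, stay open as well, and were not tested.

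Chance is an unlikely source of the counts of calls in the 2 comparisons of mut_HdS: of 100 splits of the 10 libraries, the real one included, 1 gave as many as the 137 calls of mut_HdS against mut_dHdS (highest other 86) and 1 as many as the 142 of mut_HdS against WT_HS (highest other 95). With the real split always among them, 1 of 100 is the smallest share that could be found. For WT_HS against mut_dHdS, 2 of 100 splits gave at least its 2 calls. The other of these gave 3, more than the real split, so chance stays a possible source of that count. Against PCR pools of different composition unrelated to the reading frame, 15 of 22 hok nonsense and 2 of 94 hok synonymous substitutions were called (Fisher's exact p = 7.36e-12). That test takes each substitution as a separate unit, though all come from the same libraries, so its p overstates the evidence. With the correlation of 0.172 estimated within the nonsense list, the camera p of that list was 0.00377. Against scaling as the source of the higher calls, 103 were still called higher with library totals alone. Outside both reading frames, WT_HS against mut_dHdS gave 1 call where mut_HdS against mut_dHdS gave 51, but a fault of the mut_HdS pool alone cannot be told apart from the group if its replicates share a pool, which the labels do not state. Within the reading frame, loss of Hok function under selection may underlie the calls, a hypothesis not tested in other libraries.

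Calls outside both reading frames lay in short stretches, 1 of them an inverted repeat after the hok stop codon: 45 higher calls among 592 made 100 pairs within 5 nt, where 10000 random draws gave a mean of 36.0 and at most 68 (permutation p = 0.0001, the smallest they can give). Against errors at inverted repeats in general, 16 of 41 substitutions in the arms of the first repeat were called and 0 of 40 with edgeR in those of the second, in a comparison with 228 unadjusted p under 0.05 and 181 DESeq2 and 115 limma-voom calls (Fisher's exact p = 4.94e-06). That p, too, takes substitutions of the same libraries as separate units, and the first repeat was singled out by its calls, so the p overstates the evidence. The repeats differ in arm sequence and in the spacing of the arms, so the second cannot speak for errors particular to the first. Loss of base pairing between the arms is a candidate explanation: the 8 substitutions that keep a G-U pair (7 from C to T, and A388G) had a median log2 fold change of -0.64 against 2.43 for the 33 that break a pair, a difference of -3.07 that did not pass (permutation p = 0.0595, or 0.107 with C to T alone as first coded), and C to T was lower than the mean of the others at 7 of 7 C positions, by a mean of -2.77 (exact sign-flip p = 0.0156). A high background of C-to-T errors could hide the change of C to T instead: its median share in mut_dHdS was 0.204%, against 0.0597% for all 106 C-to-T changes tested elsewhere, called or not (permutation p = 0.0005). Both explanations stay open, and no test here separates them. Not every pair-breaking substitution rose: 16 of the 33 were called. At the pair of positions 394 and 401, G394T rose by 3.61 ± 0.65, while C401A was at 0.31 ± 0.34 and C401G at 0.43 ± 0.27.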
